A study of Mus musculus with 12 samples.

How the data were processed

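RNA was sequenced from dissociated lumbar dorsal root ganglia (DRG) of mice that express Cre recombinase from the Advillin gene in sensory neurons together with the RiboTag allele, which puts a hemagglutinin (HA) tag on the ribosomal protein Rpl22 in cells with Cre. The 12 libraries formed 4 groups of 3: HA immunoprecipitate (IP) of naive ganglia, IP of injured ganglia, input RNA taken before the immunoprecipitation of naive ganglia, and input RNA of injured ganglia. Groups and replicate numbers were taken from the sample titles. The labels' design text speaks of 4 mice as replicates, while 3 replicates per group were analysed here, and it is not stated which animal a replicate number stands for. The p-values therefore measure the spread between these libraries, which may hold animal differences and technical differences.

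Per the labels' protocols, RNA was purified on RNeasy Mini columns and made into strand-marking libraries with a ribosomal RNA depletion kit (TruSeq Stranded Total RNA Gold). Such libraries keep unspliced and noncoding RNA. The submitters' processing notes name bcl2fastq 2.17, STAR, HTSeq and the mouse genome builds GRCm38 and mm10, without saying which step each was used for. The authors deposited raw read counts per RefSeq gene symbol for all 12 libraries. They also deposited raw read counts per short genomic interval, each with a position, strand, a repeat family or none, and a nearby 3′ untranslated region (3′ UTR) or none. How the reads were assigned to a strand, to overlapping genes or to near-identical copies is not given in the sources used here. Ribosomal protein genes, whose processed copies are scattered over the genome, and members of close gene families such as the Mrgpr receptors and the class I H2 genes are therefore uncertain where reads could be split between copies. How the intervals were selected, whether their positions count from 0 or 1, and how a read that matches many repeat copies was counted are not given either, so positions are printed as deposited on mm10, and counts of single repeat copies are uncertain.

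The gene table held 24060 entries. Of these, 27 had names turned into dates and could not be tied to a gene. They took 0.191% to 0.214% of the counts and were left out of totals and tests, which left 24033. The interval table held 205977 intervals, of which 190678 (92.57%) had an end minus start of 25, 169207 carried a repeat family, 42661 lay in or beyond a 3′ UTR, and 85606 (41.56%) had no count in any library. A further 4 of its lines were empty and were not used here. Columns that belong to no sample numbered 0. Each interval column was compared with the gene columns over 2460 genes measured in both tables, and correlated best with the gene column of its own library in each of the 12. Replicates of a group differed by far more than sampling noise, with a chi-square per degree of freedom of 4.61 to 52.4, so none were merged.

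Counts were tested with the quasi-likelihood F test of edgeR 4.0.16 (robust fit, R 4.3.3) on all 12 libraries in 1 fit with 4 group means and 8 residual degrees of freedom. Composition was scaled with trimmed mean of M values (TMM) factors, which were 0.943 to 0.977 in IP and 1.02 to 1.06 in input. Low genes were removed with filterByExpr, which left 15748 genes, and p-values were adjusted with the Benjamini-Hochberg method at a threshold of 0.05. The 5 comparisons were injured against naive in IP, injured against naive in input, IP against input in naive ganglia, IP against input in injured ganglia, and the interaction, which is the injury change in IP minus that in input. Levels are CPM (counts scaled to the library size and TMM factor), and log2 changes come with their standard errors (SE). Gene positions came from RefSeq on GRCm38, with 14898 genes matched by symbol, 795 by synonym and 55 unmatched.

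Gene lists were fixed before the data were examined and tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison. Camera with an estimated correlation stands beside it. The 29 lists were pan-neuronal, regeneration-associated, nociceptor and itch neuron, mechanoreceptor and proprioceptor, voltage-gated potassium channel, voltage-gated sodium and calcium channel, synaptic vesicle, GABA-A with opioid and neuropeptide receptor, growth cone cytoskeleton, axonal transport and importin, myelinating Schwann cell, satellite glia, injury-responsive glia, macrophage, lymphocyte and neutrophil, endothelium and pericyte, fibroblast and perineurium, erythrocyte, proliferation, cholesterol synthesis, integrated stress and unfolded protein response, ribosomal protein, oxidative phosphorylation, mitochondrially encoded, nuclear noncoding RNA, immediate early, interferon response, class I antigen presentation, and cytokine and chemokine. Of the 13 mitochondrially encoded genes, 0 were among the genes tested, so that list has no result. Some genes stand in 2 lists, such as Atf3 in the regeneration-associated and immediate early lists.

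Intervals with a repeat family were tested in the same way, with library sizes and TMM factors of the gene table, for single intervals and for sums per family. Family sums were tested from 100 counts over all libraries, and of those with at least 0.1% of repeat counts at most 8 were to be named. Intervals were split afterwards by the annotation into those inside exons on the same strand and all others. A fold against a group with no counts is given as a lower bound from a floor of 3 counts over the group, and ratios of few counts carry a 95% counting interval. Both cover counting error only.

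Genes were named by a rule set before the data were examined. In each injury comparison, these were the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the 3 injured and 3 naive libraries, a separation that chance gives in 10% of cases. In the other comparisons these were the 6 largest each way. For each list, up to 4 members past the threshold with at least 1 CPM were taken. Rpl22, Avil, Atf3, Jun, Sox11, Sprr1a, Gap43, Gal, Npy and Csf1 were always included. For intervals, the 3 largest each way with a mean of at least 10 counts were taken. Some genes that meet this rule are not reported here. A gene or interval that the text names outside this rule was chosen after its values were seen.

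The test was tried on counts simulated from the fit, with a change put into IP only for 200 genes or intervals. Over 15748 genes, 31.3% of 1.5-fold, 80.6% of 2-fold and 87.9% of 4-fold changes were recovered, and 1.48% of 135 calls were false. Over 23255 intervals, with or without a repeat family and scaled by TMM factors of the intervals themselves, 1.49%, 37.3% and 68.2% were recovered, and 10.1% of 79 calls were false, so single intervals carry less weight than genes. A simulated list of genes given a 2-fold rise gave a camera p of 4.44e-125 and an unchanged list 0.427. Simulated genes were drawn independently of each other, so this does not test camera on lists whose genes vary together.

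Replicate numbers were checked for pairing before any blocked result was viewed. Within IP, deviations of naive and injured libraries of a number from their group means correlated at 0.447, 0.319 and 0.191, and within input at 0.273, 0.423 and 0.597. All were over 0.1, so the numbers were taken to pair naive with injured libraries within each fraction. This pairing of numbers comes from the data. The design text takes both ganglia from each animal but does not say which animal a number stands for. A fit with a separate replicate term for IP and for input was added after that check. The main results kept the fit set beforehand, without a block, so their p-values do not use this pairing.

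Alternatives set beforehand were DESeq2 size factors or library size alone in place of TMM, no filter or a stricter one (1 CPM in 3 libraries), DESeq2 1.42.0, limma-voom, the replicate number as a block, a fit of only the 6 libraries compared, and leaving out each library in turn. After the data were seen, fits without the naive libraries numbered 2, without the input libraries numbered 3 and without the IP libraries numbered 1 were added. Splits of the libraries, the real one included, numbered 10 for groups of 3 against 3, and 60 relabelings, the real one included, were drawn for the interaction.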

Results

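Mice in which Advillin-Cre puts an HA tag on the ribosomes of sensory neurons received a crush of 1 sciatic nerve, and lumbar DRG were taken 3 days later. RNA bound to the tagged ribosomes (IP) and total RNA of the dissociated ganglia (input) were sequenced from injured and naive ganglia, with 3 libraries in each of 4 groups. The design text takes both ganglia from each animal, so naive ganglia may come from the uncrushed side of crushed mice. The gene table held 33574292 to 36409731 counts per library in naive IP and 41157574 to 42073883 in injured IP. In input it held 29497771 to 33086433 counts in naive and 29534269 to 31484191 in injured ganglia. Each comparison of groups below sets 3 libraries against 3, and the interaction uses all 12. Values are means ± SD in CPM. Unless another fit is named, p-values rest on a spread estimated over all 12 libraries, not only over those compared. In a principal component analysis, the components held 66.04%, 18.01% and 4.491% of the variance, and on the last of these the input libraries numbered 3 stood at 23.2 and 34.1 while the other input libraries lay between -9.71 and -20.8.

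In naive ganglia, the IP held more neuronal RNA and far less RNA of other cells than the input. Avil, an actin regulator of sensory neurons that drives the Cre, was higher in IP by 0.45 log2 (adjusted p = 0.000757), Syn1, a synaptic vesicle protein, by 0.73, and App, the amyloid precursor, by 1.00 (SE 0.105, adjusted p = 9.63e-06, 840.2 CPM in input and 1682 CPM in IP). Apoe, a lipid carrier of satellite glia and macrophages, was lower by 3.33 log2 (adjusted p = 0.000202, 2573 CPM in input and 255.1 CPM in IP). Rpl22, the tagged ribosomal protein, was lower in IP by 0.25 log2 (adjusted p = 0.00448), a call lost without input naive 3 (adjusted p = 0.0685).

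The largest enrichments in naive ganglia were Rspo4, a Wnt agonist, at 1.11 log2, Clip3, a microtubule linker, at 1.09 (from 213.7 to 453.7 CPM), Fam167a at 1.07, Cep162, a centrosomal protein, at 1.05 and Ccdc68 at 1.02, beside App. The deepest depletions were Rmrp, a nuclear and mitochondrial RNA, at -4.29 (SE 0.819, adjusted p = 0.0012; -5.98 without IP naive 2), Fxyd3, an ion pump regulator, at -3.71, Egr2, the transcription factor of myelination, at -3.60, Ptgds, a prostaglandin synthase of meninges and perineurium, at -3.57, Pmp2, a myelin lipid binder, at -3.52 and Mgp, a matrix protein, at -3.50. In injured ganglia the list was led by Rspo4 at 1.17, App at 1.17 (adjusted p = 3.92e-06), Ccdc68 at 1.16, Rab27b, a vesicle GTPase, at 1.15, Cysltr2, a leukotriene receptor, at 1.12 and Cdh9 at 1.06. The deepest depletions there were Rmrp at -4.53 (-5.45 without IP injury 2), Ptgds at -3.56 (-4.16 without IP injury 2), Egr2 at -3.48, Mfap5 at -3.46, Ecscr at -3.44 and Rarres2 at -3.40. Avil was higher in injured IP by 0.51 log2 (adjusted p = 0.000264), and Rpl22 was lower, at -0.23 (adjusted p = 0.00634; 0.0516 without the IP libraries numbered 1). Atf3, Sprr1a, Gap43 and Npy passed the threshold in neither state.

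Lists of glia and other cells were lower in IP, and several neuronal lists were higher. Of 25 pan-neuronal genes, 15 were higher in naive IP and 0 lower (camera adjusted p = 3.19e-06, and adjusted p = 0.0683 with an estimated correlation; 16 and 0 adjusted over the list alone), with a median of 0.368 log2. Of 34 nociceptor and itch neuron genes 24 were higher and 1 lower (1.45e-08, and 0.0532 with an estimated correlation). Mechanoreceptor and proprioceptor genes were not called as a list, with 6 higher and 5 lower of 24 in naive (0.145) and 7 and 3 in injured ganglia (0.164), and 4 and 7 in each state with library size alone as scaling. All 19 myelinating Schwann cell genes were lower (3.15e-22; 0.0733 with an estimated correlation; median -2.98), as were 18 of 21 satellite glia genes (2.06e-11; 0.0733; median -2.79), 28 of 29 macrophage genes (1.03e-10; 0.206; median -2.83), 20 of 22 endothelium and pericyte genes (3.92e-15; 0.0733) and 20 of 21 fibroblast and perineurium genes (4.77e-17; 0.0733), where 1 was higher. Of 80 ribosomal protein genes, 74 were lower and 0 higher (2.4e-17; 0.229 with an estimated correlation; median -0.647). Of 15 nuclear noncoding RNAs 10 were lower and 1 higher (7.56e-06; 0.0867), among them Malat1 at -1.89 log2 (adjusted p = 3.87e-05). Of 26 axonal transport and importin genes 15 were higher and 1 lower in naive IP (0.000297, and 0.0532 with an estimated correlation). In injured ganglia 20 were higher and 0 lower, and this call held with an estimated correlation (3.18e-05; 0.0391 with it).

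**Figure D1:**
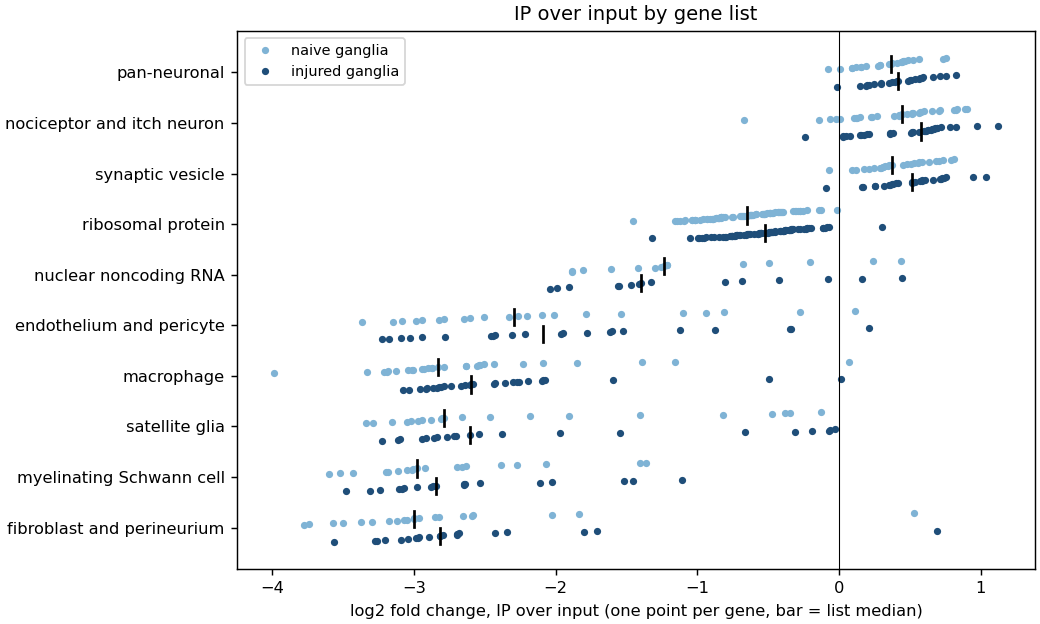
Log2 ratio of IP over input for each gene of 10 lists, in naive (light) and injured (dark) ganglia. Bars mark medians.

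By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 6474 of 15748 genes differed between IP and input in naive ganglia at an adjusted p under 0.05, 2383 higher and 4091 lower in IP, and 23 and 2505 of them by at least 1 log2. In injured ganglia 7230 differed, 3363 higher and 3867 lower, with 35 and 2387 by at least 1 log2. With library size alone as scaling the higher group shrank to 1368 against 4760 in naive ganglia (22.32% of calls in place of 36.81%) and to 1521 against 4845 in injured ganglia (23.89% in place of 46.51%), with median shifts of -0.106 and -0.105 log2. With that scaling, the neuronal lists kept positive medians. Without the input libraries numbered 3 the larger group in naive ganglia turned from lower to higher in IP (4473 higher and 3895 lower of 8368).

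After crush, the transcripts bound to tagged ribosomes changed most at genes of the axotomy response. Sprr1a, a small proline-rich protein made by injured neurons (chromosome 3, 92483954 to 92485881 on GRCm38), rose by 6.77 log2 (SE 0.765, adjusted p = 6.15e-05), from 1.17 ± 1.69 to 129.3 ± 10.3 CPM. Atf3, a stress transcription factor (chromosome 1, 191170296 to 191183333), rose by 4.96 log2 (SE 0.517, adjusted p = 3.13e-05), from 19.2 ± 14.7 to 597.1 ± 16.6 CPM. Npy, a neuropeptide (chromosome 6, 49822710 to 49829507), rose by 5.73 (SE 0.608, adjusted p = 3.58e-05), from 1.15 ± 1.33 to 62.1 ± 12.2 CPM, and the neuropeptide Gal rose by 4.67 (SE 0.350, adjusted p = 1.91e-06). Csf1, a growth factor for macrophages and microglia, rose by 2.84 (SE 0.124, adjusted p = 2.29e-08), from 15.5 ± 2.11 to 111 ± 7.09 CPM.

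The other large rises in IP were Lipn, a lipase, at 6.58 log2 (SE 0.284, adjusted p = 2.29e-08), Slc6a4, the serotonin transporter, at 6.18, Cckbr, a cholecystokinin receptor, at 5.55, Gpr151, an orphan receptor, at 5.17, Ecel1, a neuronal peptidase, at 5.14 and Tmem88b at 5.12. The transcription factors Sox11 and Jun rose by 3.12 and 1.37, and Gap43, a growth cone protein, rose from 157.4 to 445 CPM (adjusted p = 1.93e-07). Rpl22 and Avil were not called, at 0.08 log2 (adjusted p = 0.388) and -0.01 (adjusted p = 0.958). The naive libraries numbered 2 held more of several of these transcripts than the other naive libraries, and without them the rise was 9.36 log2 for Sprr1a, 7.53 for Slc6a4, 7.36 for Cckbr, 7.32 for Npy, 7.28 for Lipn, 6.52 for Ecel1, 5.92 for Tmem88b, 5.845 for Gpr151, 5.80 for Atf3 and 5.27 for Gal. Falls were smaller. Comp, a matrix protein, fell by 1.43 log2 (SE 0.140, adjusted p = 1.23e-05). Bambi, a TGF-beta pseudoreceptor, fell by 1.19, Fam196b by 1.18, Nog, a BMP antagonist, by 1.12 and Vstm2b by 1.12. Htr3b, a serotonin receptor subunit (chromosome 9, 48935008 to 48964990), fell by 1.09, Agtr1b, an angiotensin receptor, by 1.09, Hoxb6 by 1.09, Thrsp by 1.07 and Oprd1, the delta opioid receptor (chromosome 4, 132110188 to 132144486), by 1.05 (adjusted p = 5.43e-06).

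**Figure D2:**
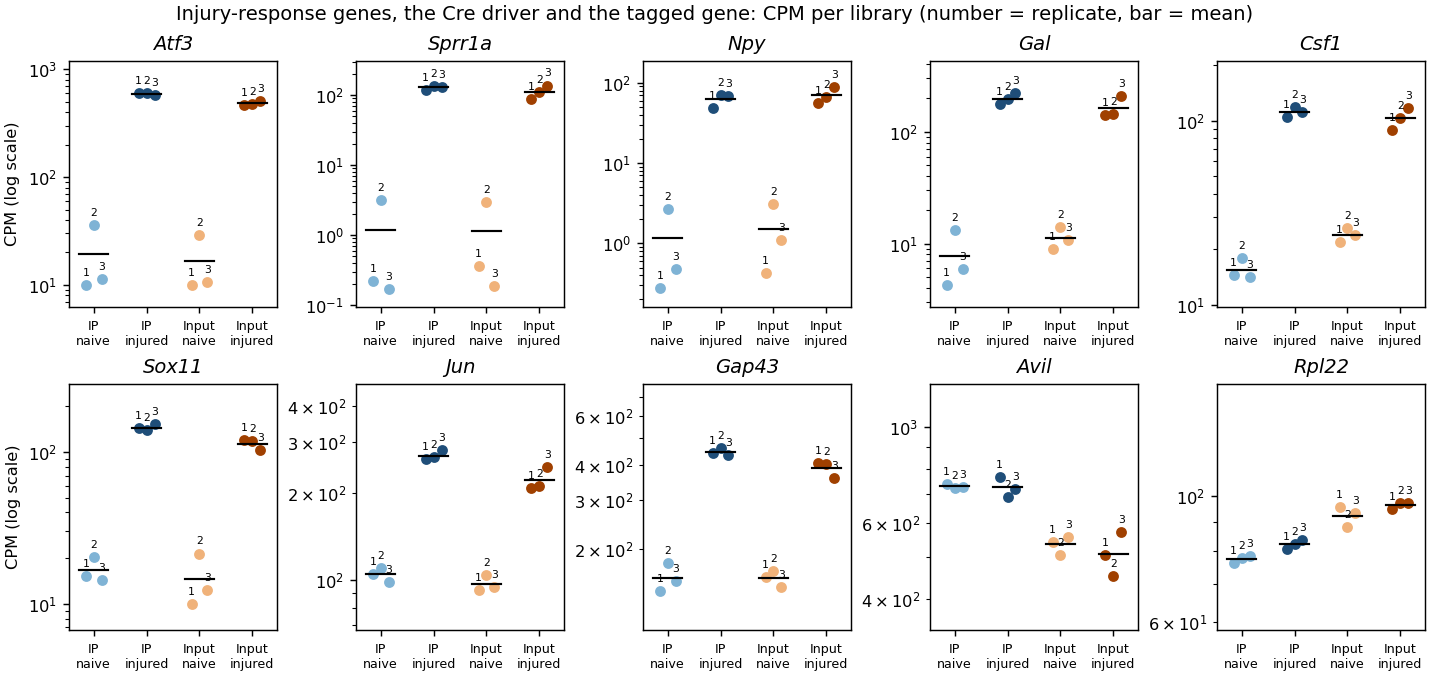
CPM of 10 genes in each library on a log scale. Digits are replicate numbers and bars are group means.

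Most regeneration-associated and growth cone genes rose in IP, and most voltage-gated potassium channel genes fell. Of 47 regeneration-associated genes, 41 rose and 0 fell in IP (camera adjusted p = 3.05e-85; 0.00728 with an estimated correlation; 45 and 0 adjusted over the list alone), among them the tubulin Tubb6 at 3.67 log2, the tubulin regulator Stmn4 at 3.06 and the calcium channel subunit Cacna2d1 at 1.34. Of 32 growth cone cytoskeleton genes 21 rose and 0 fell (1.45e-19; 0.0269 with an estimated correlation), with Tuba1c at 2.24. Of 35 voltage-gated potassium channel genes 22 fell and 1 rose (2.59e-11; 0.0158 with an estimated correlation), with Kcna2 falling by 0.75. GABA-A, opioid and neuropeptide receptors fell in 13 of 27 cases and rose in 4 (0.000101; 0.035 with an estimated correlation), with a median of -0.378 and a mean of -0.0413, and Oprk1, the kappa opioid receptor, fell by 1.05 while Gabrg1 rose by 1.07. Nociceptor and itch neuron genes fell in 20 of 34 cases and rose in 4 (2.16e-05, and adjusted p = 0.0794 with an estimated correlation), among them Sst at -0.80, Mrgprx1 at -0.73 and the cold receptor Trpm8 at -0.71, while the receptor Gfra3 rose by 0.86. Mechanoreceptor and proprioceptor genes fell in 11 of 24 cases and rose in 2 (0.000116, and adjusted p = 0.105 with an estimated correlation), with Mafa at -1.27 and Etv1 at -0.88 against Gfra1 at 1.43.

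The calls of other neuronal and metabolic lists in IP did not hold with an estimated correlation, and some of these lists were not called. Of 27 sodium and calcium channel genes 7 fell and 2 rose (0.00102, and adjusted p = 0.275 with an estimated correlation), with Scn1a at -0.62. Of 27 synaptic vesicle genes 6 fell and 0 rose (0.00285, and adjusted p = 0.417 with an estimated correlation). Pan-neuronal genes went both ways, 4 up and 5 down (0.935; median -0.0164, mean 0.0454), as did axonal transport and importin genes, 5 up and 2 down of 26 (0.833). Of 24 cholesterol synthesis genes 12 rose and 0 fell (0.000778, and adjusted p = 0.192 with an estimated correlation), with Hsd17b7 at 1.61. Of 29 genes of the integrated stress and unfolded protein response 15 rose and 0 fell (1.26e-05, and adjusted p = 0.08 with an estimated correlation), with Chac1 at 1.65 and Trib3 at 1.13. Ribosomal protein genes rose in 30 of 80 cases and fell in 0 (8.77e-08, and adjusted p = 0.679 with an estimated correlation; 59 and 0 adjusted over the list alone). Immediate early genes rose in 9 of 21 cases and fell in 0 (0.000497, and adjusted p = 0.292 with an estimated correlation), with Btg2 at 1.22. Oxidative phosphorylation genes gave 0 calls of 50 by edgeR, 2 at an unadjusted p under 0.05, 1 by DESeq2 and 1 by limma-voom (0.219). Nuclear noncoding RNAs gave 0 rises and 1 fall of 15, Pvt1 at -0.57 (adjusted p = 0.00485; 0.0501 without the IP libraries numbered 1; list 0.674; the camera direction was down while the median was 0.0312 and the mean 0.0494).

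Some genes of other cells and of immune signalling rose in IP, in lists that were not called or whose calls did not hold with an estimated correlation. Of 29 macrophage genes 7 rose and 0 fell (0.00117, and adjusted p = 0.693 with an estimated correlation; 15 and 0 adjusted over the list alone), with Csf1r, the receptor for Csf1, at 1.44, and these genes were lower in naive IP than in input in 28 of 29 cases. Cytokine and chemokine genes rose in 7 of 18 cases and fell in 0 (1.2e-05, and adjusted p = 0.245 with an estimated correlation). Interferon response genes rose in 12 of 28 cases and fell in 0 (0.00282, and adjusted p = 0.693 with an estimated correlation), with Mx2 at 1.11. Proliferation genes rose in 5 of 30 cases and fell in 0 (0.00465, and adjusted p = 0.531 with an estimated correlation), with Prc1 at 2.71. Satellite glia genes rose in 3 of 21 cases and fell in 0 (0.18; 0.00335 with replicate number as a block within fraction), with Aldh1l1 at 1.11 and Glul at 0.92. Class I antigen presentation genes rose in 3 of 15 cases and fell in 0 (0.264; 0.034 with the block within fraction). Endothelium and pericyte genes rose in 2 of 22 cases and fell in 0 (0.264), myelinating Schwann cell genes in 1 of 19 and 0 (0.658), with Gldn at 1.03. Injury-responsive glia genes rose in 2 of 15 cases against 1 fall (0.985), with Sema4f at 0.69 and Cd9 at -0.32. Fibroblast and perineurium genes gave 0 calls of 21 by edgeR, 2 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom (0.719; 0.0498 with the block within fraction). Lymphocyte and neutrophil genes gave 0 of 16 by edgeR, 1 at an unadjusted p under 0.05, and 0 by DESeq2 and by limma-voom (0.985). Erythrocyte genes gave 0 of 5 by all 3 tools and at an unadjusted p under 0.05 (0.805; median 0.0592, mean -0.359).

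In all, 2939 of 15748 genes changed in IP at an adjusted p under 0.05, 1818 higher and 1121 lower, with 616 and 56 by at least 1 log2. With replicate number as a block within fraction the count was 6586 (3749 higher, 2837 lower), with only the 6 IP libraries 4736 (2544 and 2192), and without the IP libraries numbered 1 it was 1748 (1237 and 511). In the simulation, where only 200 genes changed, a 1.5-fold change was recovered in 31.3% of cases. With more genes changed the adjusted threshold is less strict, so this share need not hold here. Small changes may still be undercounted.

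In input RNA most of the same genes led. Sprr1a rose by 6.56 log2 (SE 0.764, adjusted p = 0.000119), from 1.16 ± 1.54 to 112.3 ± 24.2 CPM, Atf3 by 4.87 (SE 0.517, adjusted p = 5.7e-05), from 16.6 ± 10.8 to 486.7 ± 19.7 CPM, Gal by 3.87 (SE 0.336, adjusted p = 1.15e-05) and Csf1 by 2.11 (SE 0.120, adjusted p = 3.42e-07). Lipn rose by 6.29, Npy by 5.49 and Gpr151 by 5.19. Further rises were those of Cckbr by 4.97, Wfdc3, a protease inhibitor, by 4.67, Ecel1 by 4.60, Slc6a4 by 4.57, Sox11 by 2.95, Gap43 by 1.31 and Jun by 1.19. Rpl22, at 0.06 log2 (adjusted p = 0.548), and Avil, at -0.07 (adjusted p = 0.651), were not called. Without the naive libraries numbered 2 the rises were 8.68 for Sprr1a, 6.49 for Npy, 6.35 for Cckbr, 5.83 for Gpr151, 5.56 for Atf3, 5.46 for Ecel1 and 5.22 for Slc6a4. Kcnmb1, a potassium channel subunit, fell by 1.19 log2 (SE 0.110, adjusted p = 1.3e-05), Glb1l2 by 1.13, Htr3b by 1.09, Oprd1 by 1.06 and Vstm2b by 1.04. Tmem196 fell by 1.24 (adjusted p = 0.007; 0.0562 with only the 6 input libraries) and Vwc2l by 1.10 (adjusted p = 0.00734; 0.0632 with these 6). The muscle genes Acta1, Myh4 and Ttn fell by 1.22, 1.17 and 1.02, where Myh4 lost its call (adjusted p = 0.0213) without input naive 1 (0.0633), input naive 3 (0.0699) or input injury 2 (0.0608).

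**Figure D3:**
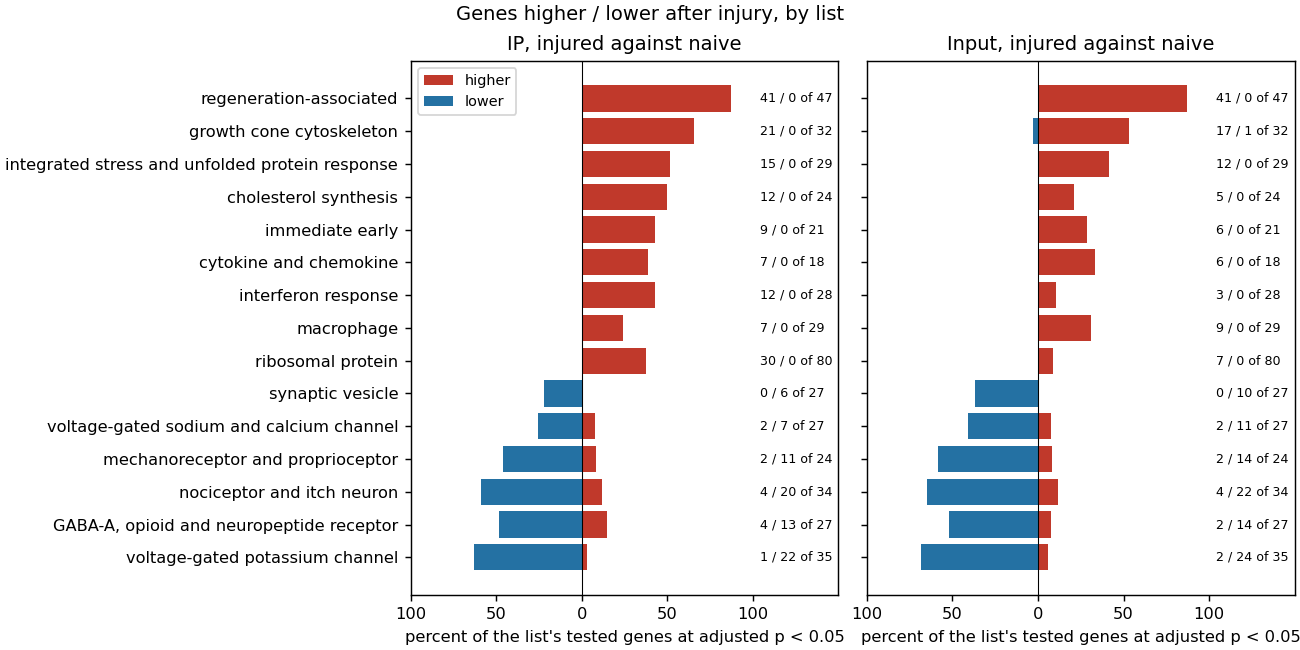
Percent of tested genes of 15 lists that were higher or lower after injury at an adjusted p under 0.05, in IP (left) and input (right). Digits give higher and lower counts and the genes tested.

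The regeneration-associated, growth cone and potassium channel lists were called in input as in IP. Regeneration-associated genes rose in 41 of 47 cases and fell in 0 (2.34e-91; 0.00602 with an estimated correlation). Growth cone cytoskeleton genes rose in 17 of 32 and fell in 1 (2.26e-18; 0.026 with an estimated correlation). Potassium channel genes fell in 24 of 35 and rose in 2 (2.41e-14; 0.00814 with an estimated correlation), with Kcnh7 at -0.99 and Kcnh5 at -0.87. GABA-A, opioid and neuropeptide receptors fell in 14 of 27 and rose in 2 (1.25e-06; 0.0136 with an estimated correlation), with Oprk1 at -1.12 and Htr3a at -0.88. Nociceptor and itch neuron genes fell in 22 of 34 and rose in 4 (2.42e-07; 0.0356 with an estimated correlation), with Mrgprx1 at -0.85 and Trpm8 at -0.82. Mechanoreceptor and proprioceptor genes fell in 14 of 24 and rose in 2 (2.59e-05, and adjusted p = 0.073 with an estimated correlation). Sodium and calcium channel genes fell in 11 of 27 and rose in 2 (6.59e-05, and adjusted p = 0.167 with an estimated correlation). Synaptic vesicle genes fell in 10 of 27 and rose in 0 (7.52e-05, and adjusted p = 0.237 with an estimated correlation), with Cplx2 at -0.52. Pan-neuronal genes rose in 4 and fell in 8 of 25 cases (0.626), with Stmn2 at 0.52 and Rbfox3 at -0.44. Axonal transport and importin genes rose in 2 and fell in 3 of 26 (0.639), with Kpna2 at 0.65.

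Some immune and proliferation genes rose in input, in lists that were not called or whose calls did not hold with an estimated correlation. Macrophage genes rose in 9 of 29 cases and fell in 0 (2.59e-05, and adjusted p = 0.541 with an estimated correlation; 16 and 0 adjusted over the list alone), with the mannose receptor Mrc1 at 1.33 log2, from 25.9 to 65.1 CPM. Proliferation genes rose in 7 of 30 and fell in 0 (3.26e-07, and adjusted p = 0.167 with an estimated correlation), with Prc1 at 1.88. Cytokine and chemokine genes rose in 6 of 18 cases and fell in 0 (3.55e-05, and adjusted p = 0.237 with an estimated correlation). Immediate early genes rose in 6 of 21 cases and fell in 0 (0.000146, and adjusted p = 0.237 with an estimated correlation), with Fosl2 at 0.87. Interferon response genes rose in 3 of 28 cases and fell in 0 (0.00425, and adjusted p = 0.713 with an estimated correlation), with Mx2 at 0.94. The integrated stress and unfolded protein response rose in 12 of 29 and fell in 0 (0.000218, and adjusted p = 0.163 with an estimated correlation), with Chac1 at 1.65. Ribosomal protein genes rose in 7 of 80 and fell in 0 (3.53e-05, and adjusted p = 0.713 with an estimated correlation; 1 and 0 adjusted over the list alone), with Rpl35 at 0.50. Cholesterol synthesis genes rose in 5 of 24 and fell in 0 (0.0613; 0.00714 with the block within fraction), and antigen presentation genes in 1 of 15 and 0 (0.053; 0.00556 with 1 block over both fractions, 0.00227 with the block within fraction). Changes were few in satellite glia genes in 2 of 21 against 1 fall (0.652), injury-responsive glia genes in 1 of 15 against 1 fall (0.864), and endothelium and pericyte genes in 1 of 22 and 0 (0.385). Fibroblast and perineurium genes gave 0 rises and 1 fall of 21, Moxd1 at -0.39 (0.864), oxidative phosphorylation genes 0 rises and 2 falls of 50 (0.076; 0.0474 with the block within fraction), and nuclear noncoding RNAs 0 rises and 1 fall of 15 (0.757). Myelinating Schwann cell genes gave 0 calls of 19 (0.757), and Mbp stood at -0.01 log2. Erythrocyte genes gave 0 of 5 (0.864), and for both lists edgeR, an unadjusted p under 0.05, DESeq2 and limma-voom each gave 0. Lymphocyte and neutrophil genes gave 0 of 16 by edgeR, DESeq2 and limma-voom, and 1 at an unadjusted p under 0.05 (0.711).

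In input 2526 genes changed, 1226 higher and 1300 lower, with 409 and 66 by at least 1 log2. Which group was larger depended on the setting. More genes were higher than lower without input naive 3 (1687 and 753), without the input libraries numbered 3 (1936 and 1003), with DESeq2 (1540 and 1252) and with DESeq2 size factors (1372 and 1081, 55.93% higher in place of 48.54%). More were lower with limma-voom (1261 and 1284) and without input injury 3 (1097 and 1556). With the block within fraction 6237 genes were called (2753 and 3484), with only the 6 input libraries 1335 (858 and 477), without input naive 1 1524 (764 and 760), and without the naive libraries numbered 2 1669 (867 and 802).

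Injury changes in IP and input went together. Across 15748 genes the log2 changes correlated at r = 0.8215 (Spearman 0.7756), and at 0.9333 among genes with at least 5 CPM, where genes are not independent replicates. Of the calls, 1088 rose in both fractions, against 141.5 for independent lists, 847 fell in both, against 92.54, and 0 went in opposite directions. Genes enriched in IP over both states numbered 4271, of which 452 rose and 566 fell in IP after injury (median -0.04 log2) and 317 rose and 767 fell in input (median -0.10). Of 4853 depleted genes, 651 rose and 177 fell in IP (median 0.145) and 385 rose and 102 fell in input (median 0.0897). Of 6624 genes in neither class, 715 rose and 378 fell in IP and 524 rose and 431 fell in input.

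**Figure D4:**
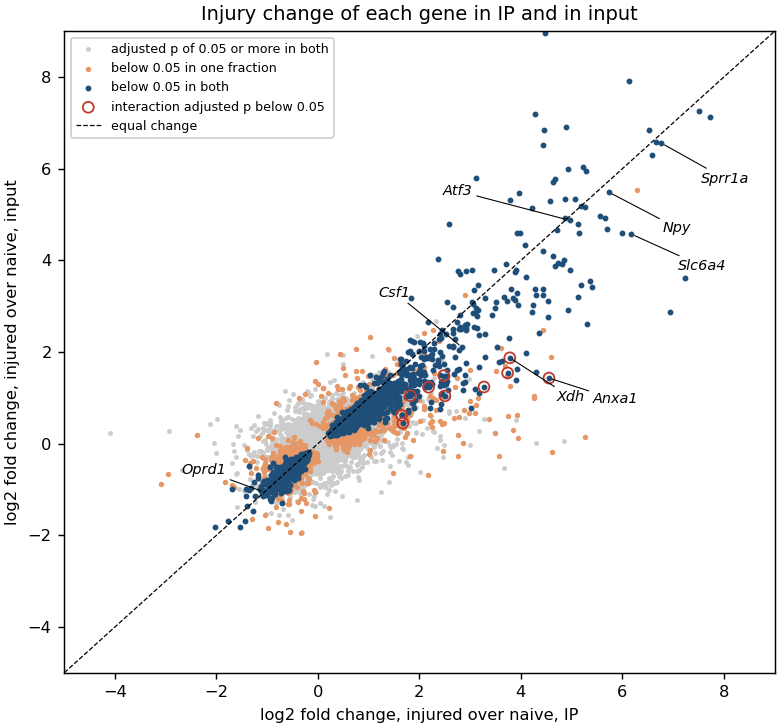
Log2 injury change in IP against that in input for each gene. Orange genes were called in 1 fraction, blue in both, red circles mark genes whose change differed between fractions, and the dashed line is equal change.

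For 10 genes the log2 injury change differed between fractions, each with a larger log2 rise in IP. Anxa1, a phospholipid-binding protein, rose from 1.594 to 37.85 CPM in IP and from 12.75 to 34.36 CPM in input, a difference of 3.12 log2 (SE 0.414, adjusted p = 0.0215). Trp53i11, a p53 target, differed by 2.20 (adjusted p = 0.0179), Pxdc1 by 2.04 (adjusted p = 0.0087), Xdh, xanthine dehydrogenase, by 1.91 (adjusted p = 0.0235), Clic4, a chloride channel, by 1.23 (adjusted p = 0.0179) and Rab31, a vesicle GTPase, by 1.03 (adjusted p = 0.0215). The other 4, chosen after their values were seen, were Tmem98, Cdkn1a, Myo10 and Bach1. Csf1 differed by 0.73 log2 and was not called (adjusted p = 0.306; 2.54e-06 with the block within fraction).

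The interaction test called 10 of 15748 genes higher and 0 lower. At an unadjusted p under 0.05 there were 488. That is fewer than this threshold gives on average where no gene differs, so the 488 add no support. DESeq2 called 44 (41 and 3) and limma-voom 9. The block within fraction called 282 (262 and 20), and there Anxa1 was not called (adjusted p = 0.087). The count fell to 0 without IP injury 3 or input injury 1, to 1 without IP naive 3, IP injury 2, input naive 3 or input injury 2, to 3 without input naive 1, to 4 without input naive 2 and to 5 without IP naive 1. Of the 12 ways to leave out 1 library, 10 ended the call of Rab31 (adjusted p from 0.0505 to 0.101), 8 that of Xdh (0.0631 to 0.119), 7 those of Clic4 (0.0528 to 0.0862) and Anxa1 (0.0625 to 0.105), 6 that of Trp53i11 (0.0625 to 0.0862) and 2 that of Pxdc1 (0.0536 and 0.056). Among lists, camera called regeneration-associated (0.000172), cholesterol synthesis (0.00108), ribosomal protein (0.00108), growth cone (0.0165), cytokine and chemokine (0.0205) and stress response genes (0.0264) as rising more in IP and proliferation genes as rising less (0.00873), and with an estimated correlation the adjusted p was 0.762 or more for each. With the block within fraction, satellite glia (2.24e-06), axonal transport and importin (0.0124), pan-neuronal (0.0152) and nuclear noncoding RNA (0.0483) were called as well. That fit was run with the preset correlation only, so it is not known whether these calls hold with an estimated one.

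Repeat-derived RNA was measured in short intervals. B2, a short interspersed element transcribed by RNA polymerase III, summed outside exons to 1314 ± 171 CPM in naive and 2066 ± 165 CPM in injured input, a rise of 0.65 log2 (SE 0.226, adjusted p = 0.222; 0.66 log2 and 2.03e-05 with replicate number as a block within fraction). In IP the sum went from 382.1 ± 106 to 498.1 ± 158 CPM, 0.38 log2 (SE 0.225, adjusted p = 0.636; 0.37 log2 and 0.00309 with the block within fraction). B2 inside exons changed by -0.03 and 0.01 log2, and Alu and L1 elements outside exons changed by 0.03 (adjusted p = 0.857) and -0.14 (adjusted p = 0.523) in input. B2 outside exons was lower in IP than in input by 1.78 log2 in naive ganglia (adjusted p = 0.000193). Over all places it was lower by 1.31 log2 there (adjusted p = 0.000144), and with the totals of the repeat table itself as scaling it was higher by 1.126 (adjusted p = 0.000954). Over all places B2 rose by 0.55 log2 in input (SE 0.158, adjusted p = 0.0812; 0.00479 with 1 block over both fractions, 2.2e-05 with the block within fraction) and by 0.24 in IP (adjusted p = 0.665; 0.0189 with the block within fraction).

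**Figure D5:**
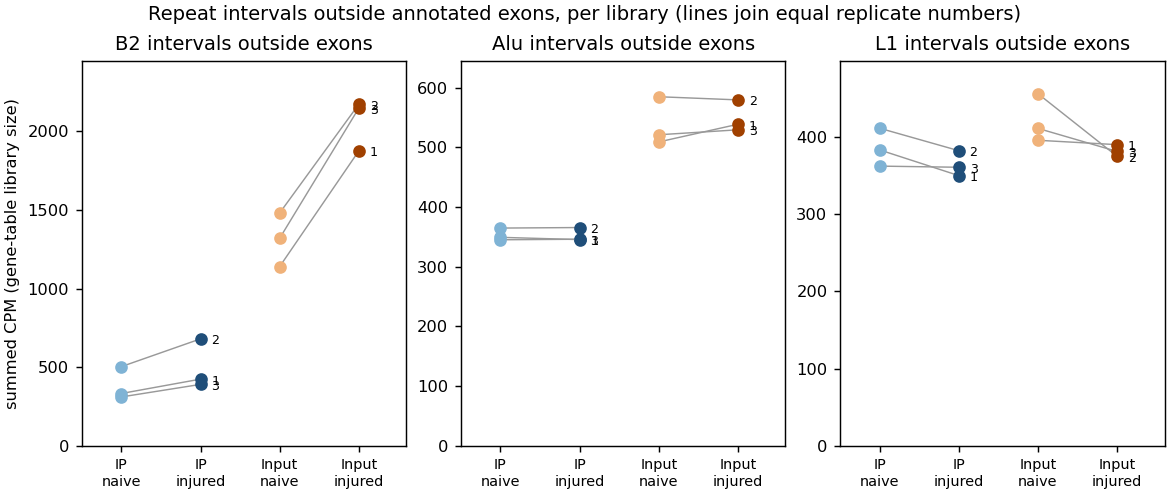
Summed CPM of B2, Alu and L1 intervals outside exons in each library. Lines join equal replicate numbers.

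Of 4777 intervals tested, 198 changed in input after injury, 175 higher and 23 lower, and of the 1250 B2 intervals among them 140 were higher and 1 lower. In IP 55 changed, 53 higher and 2 lower, with 14 and 0 among B2. Between fractions, 981 intervals differed in naive ganglia (71 higher and 910 lower in IP) and 1391 in injured ganglia (207 and 1184). These directions rest on the scaling of the gene table, and no other scaling was run for intervals between fractions. The interaction called 0 by edgeR, the tool run on intervals. Of the 4777 intervals 144 had an unadjusted p under 0.05, also fewer than this threshold gives on average where none differs. With the block within fraction the counts were 195 in IP (121 and 74) and 445 in input (294 and 151). In IP the count was 32 without IP naive 1 and 28 without IP naive 3, and in input it was 90 without input naive 1, 121 without input naive 2 and 94 without input injury 2. In a simulation over 23255 intervals, which included those without a repeat family, a 2-fold change put into IP was recovered in 37.3% of cases, and no change was simulated in input.

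The leading B2 intervals had few or no counts in naive libraries of the fraction named. That on the minus strand of chromosome 4 from 11255302 to 11255332, away from annotated genes, went from 0 to 28 counts in IP, at least 8.05-fold (adjusted p = 0.00507), and in input it went from 0.2051 to 0.8403 CPM. That on the minus strand of chromosome 12 from 104608927 to 104608952 went from 4 to 162 counts in input, a ratio of 40.3 (15.5 to 150 by counting error, and adjusted p = 0.000133, with 6.43 log2 in place of 5.23 without input naive 2). That on chromosome 7 from 125617276 to 125617316, opposite to Il21r, a cytokine receptor gene, went from 1 to 67 counts in IP, a ratio of 57.8 (10 to 2310, and adjusted p = 0.00309; 7.30 log2 in place of 5.41 without IP naive 2). That on chromosome 4 from 107061561 to 107061586, opposite to Mrpl37, went from 1 to 109 counts in input, a ratio of 109 (19.1 to 4330, and adjusted p = 7.73e-05; 8.28 log2 in place of 6.33 without input naive 2). An endogenous retroviral (ERVL-MaLR) interval in an exon of Fgf3, a growth factor gene, on chromosome 7 from 144844409 to 144844434 went from 1 to 50 counts in input, a ratio of 49.8 (8.54 to 2010, adjusted p = 0.00121; 7.17 log2 in place of 5.22 without input naive 2). The deepest fall in input, at an L1 interval on chromosome 5 from 76517000 to 76517035, was -2.41 log2 (adjusted p = 0.0143), and without input naive 2 it was -1.76 and not called (adjusted p = 0.0987).

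Among family sums, 112 were tested, and 2 rose in IP and 3 in input, with 0 falling and 0 called for the interaction. In IP intervals labelled L1 or none rose by 0.39 log2, from 49.38 to 64.67 CPM (adjusted p = 0.0234), while the other called families combined B2 with another label and held means of 13 to 30.17 counts. Between fractions, 0 were higher and 19 lower in IP than in input in naive ganglia and 4 and 27 in injured ganglia. With the totals of the repeat table itself as scaling the direction turned, with 91 higher and 4 lower in naive and 90 and 5 in injured ganglia.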

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

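The tests of other repeat families, of both readings of the naive libraries numbered 2 and of both readings of the interaction genes were chosen after the result was seen. B2 RNA outside exons was higher in injured input by 0.65 log2, which was not called (adjusted p = 0.222), and by 0.66 log2 with replicate number as a block within fraction, a fit chosen after the data were seen, which called it (adjusted p = 2.03e-05). Each injured input library (1876 to 2173 CPM) lay above each naive one (1140 to 1481), and without a block 140 of 1250 single B2 intervals were called higher and 1 lower. Over all places the sum was called with the planned block over both fractions (adjusted p = 0.00479) and not without it (adjusted p = 0.0812). Without the 10 B2 intervals with the most counts the log2 ratio stayed at 0.655. These held only 4.81% of the counts, so leaving them out could hardly have lowered it much. As no other 10 intervals held more, this share argues against a rise held mainly by 10 or fewer intervals, and says nothing on larger sets. Among other repeat families outside exons the highest rise was 0.029, and the highest change plus 2 SE was 0.232, which argues against more unspliced or genomic sequence in the injured libraries. With the block within fraction ERVK (-0.192, adjusted p = 0.0124) and ERVL-MaLR (-0.202, adjusted p = 0.0227) fell outside exons. Counting of 1 read at several near-identical copies stays open, since the ratio was 0.656 without the 133 intervals of equal counts among 3275, and copies that share part of their reads would not be found this way. A true rise of B2 RNA may also be the source, as a hypothesis found and tested on the same libraries.

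The naive libraries numbered 2 held injury transcripts. Of 23 strongly rising IP genes, 22 were highest in naive 2, with an excess of 1.9% to 6.04% of the injured level (median 3.8%). These 23 were called genes that passed a cut on the rise and on the injured level in IP. The same cut in input was passed by 14 of them, and 13 of these 14 were highest in naive 2 in IP and input alike. Over all called genes that rose by at least 1 log2 or fell by at least 0.5, naive 2 was the naive library nearest to injury for 62% of 616 rising and 47.2% of 472 falling genes in IP and 52.6% of 409 rising genes in input. Of 565 falling genes in input this held for 32.6%, against 45% for naive 3. RNA of an injured library mixed in at 1 proportion could give this, since 1 percent, 3.74%, lay in the intervals of 21 of the 23 IP genes, and 3.71% in those of 12 of 14 input genes. Each interval was a 95% counting interval widened by the range of the other naive and of the injured libraries. An earlier criterion was that no 2 intervals part. It was replaced after its values were seen, on the ground that extremes of many intervals can part by chance, which the widening makes less likely. That criterion would have argued against mixing: Sprr1a reached up to 3.06% while Atf3 began at 3.74% in IP, and Car3 reached up to 0.762% while Nts began at 8.65% in input. Mixing and an injury response in part of that tissue therefore cannot be told apart here.

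On the log2 scale, the injury change was larger in IP than in input at Anxa1 (3.123 log2), Trp53i11 (2.196), Pxdc1 (2.036), Xdh (1.909), Tmem98 (1.461), Clic4 (1.228), Rab31 (1.031), Cdkn1a (0.995), Myo10 (0.948) and Bach1 (0.775). All 10 were lower in IP than in input in naive ganglia. The input change in CPM over the IP change had a median of 0.707 over these genes, and 5 of them lay below 0.7, the 25th percentile of 241 other rising genes. Of 10000 sets of 10 drawn from those other genes, 4.6% had a median as low, and the middle 95% of their medians ran from 0.692 to 0.905. Genes picked for a larger rise in IP would have low ratios in any case, so this leaves open whether RNA of other cells that adds a constant to input gave the difference on the log scale. The drawn sets replaced, after its value was seen, a bound on the spread of single genes, which the median had met and which a median would nearly always meet. Without the IP libraries numbered 1, 5 of the 10 kept their call, which leaves open how far these libraries decide the calls, since fewer libraries also weaken the test. The test without these libraries also replaced, after its value was seen, a bound on unadjusted p-values that all 10 met, because genes chosen for the difference would nearly always meet it.

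Among other splits of the libraries, 1 of 10 called as many genes as the real one, the real one itself, for injury in IP (2939, highest other 0), injury in input (2526, highest other 0), and IP against input in naive (6474, highest other 0) and injured ganglia (7230, highest other 0). For single repeat intervals this was also 1 of 10 in IP (55, highest other 19) and in input (198, highest other 0), and for family sums 1 in IP (2, highest other 1), 3 in input (3, highest other 6), and 1 between fractions in naive (19, highest other 0) and in injured ganglia (31, highest other 0). With 10 splits these are too few for a share under 0.05. For injury, the splits with larger counts put naive and injured libraries of a number on the same side, and among splits that part every such pair the highest other was 0 for genes, intervals and family sums. Every other split mixes the real groups, so the real difference enters its spread and tends to lower its count. A count of 0 there is therefore no measure of chance. For the interaction 3 of 60 relabelings called at least 10 genes, and the highest other called 1604. The relabelings calling more kept the real IP groups and changed only the input groups, so the injury effect in IP itself enters their count and they are no measure of chance. Of 51 relabelings that kept the real groups in neither fraction, the highest called 0, and as these mix the real groups this is no measure of chance either. Since 2 of the 3 are no measure of chance, the count of 3 neither excludes chance nor speaks for it.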

How the results depend on the processing

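The fits without the naive libraries numbered 2, the input libraries numbered 3 or the IP libraries numbered 1, and the block within fraction, were chosen after the data were seen. The cause was not tested unless named. Of 130 counts and correlations 92 stayed within 1.5 times. Of 9406 values of named genes 9021 kept their status as called or not called, 360 lost their call, 25 gained one and 0 reversed. Of 364 list results 277 kept their status, 76 lost their call and 11 gained one. A reversal was counted only where at least 1 of the fits gave a call, so any change of sign without a call is counted as kept. With the estimated correlation, 75 list results lost their call. Of 127 values of named intervals 89 kept their call and 38 lost it.

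With replicate number as a block within fraction, calls rose from 2939 to 6586 in IP, from 2526 to 6237 in input and from 10 to 282 for the interaction, and for repeat intervals from 55 to 195 in IP and from 198 to 445 in input. With 1 block over both fractions they were 3662, 3171 and 18, and 88 and 259 for intervals, with 7 family sums in input (5 higher, 2 lower). IP and input of a number were not taken to pair, since not every r passed 0.1 (0.0472 to 0.23 in injured and 0.0766 to 0.13 in naive ganglia). Still, r was above that with input libraries of other numbers, except for injured number 2 (0.0472 against 0.0607). With the block over both fractions 7264 genes differed between fractions in naive and 8105 in injured ganglia (4058 higher and 4047 lower in IP, in place of 3363 and 3867). In these comparisons the single block ended the call of the GABA-A, opioid and neuropeptide receptor list in naive ganglia (0.0473 to 0.051) and gave that of Gap43 in injured ganglia (0.0937 to 0.0405). Beyond these and the blocked values printed with the results, the block changed no other call reported here.

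With only the 6 libraries compared, 4736 genes were called in IP and 1335 in input. Without the IP libraries numbered 1 the counts were 1748 in IP and 5 for the interaction, without the naive libraries numbered 2 1669 in input, and without the input libraries numbered 3 97 repeat intervals in input. DESeq2 called 44 interaction genes. With a mean count of at least 10, 91 intervals were called in input. Leaving out 1 library gave 1964 to 2601 genes in IP, 1524 to 2653 in input, 5135 to 6394 and 6011 to 7374 between fractions in naive and injured ganglia, and 0 to 15 for the interaction, and 28 to 47 intervals in IP and 90 to 164 in input.

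With the enrichment classes split also at 1 log2, 2 enriched genes were called in IP and 4 in input after injury, and 305 and 174 depleted genes. With the totals of the repeat table itself, whose counts are dominated by structural RNA depleted in IP, the log2 ratio of IP over input turned from negative to positive: in naive ganglia Alu (2.233 log2), B2 (1.126), ERVK (2.458), L1 (2.259) and rRNA (1.977), and in injured ganglia Alu (1.997), B2 (0.558, not called) and rRNA (1.482). Of these only B2, and rRNA in injured ganglia, had been called lower. With these totals 95 families were called in each state between fractions (91 higher and 4 lower in naive, 90 and 5 in injured ganglia), and 1 for injury in IP.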

Other observations

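The checks of single libraries below were chosen after the data were seen. Sesn2, a stress-induced regulator of growth signalling, rose by 1.13 log2 in IP and 0.80 in input, and Kif22, a kinesin, rose by 2.44 and 2.48. Slc2a1, a glucose transporter in the endothelium and pericyte list, rose by 1.35 in IP and 0.89 in input, and the cells behind this rise were not tested. Among ion channels Kcnb2 fell by 0.74 in input and Kcng4 fell by 0.75 in IP.

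Satellite repeats stood at 844.8 CPM in input naive 3. IP naive 2 held 20270 CPM of signal recognition particle RNA against 1915 and 1913 in the other naive IP libraries, and IP injury 2 held 11070 against 2010 and 3708. Apoe was lowest in the IP libraries numbered 1, at 100.4 and 106.1 CPM, against 374.8 and 290 in the other naive and 413.7 and 339.4 in the other injured IP libraries.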
